A study of Ascaris suum with 28 samples.

How the data were processed

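The series measured RNA from the parasitic roundworm Ascaris suum. The 28 samples covered oocytes, zygotes from 4 regions of the uterus, embryos of known age and cell number, L1 and L2 larvae, polysome gradients of embryos and pooled tissues. Libraries were made from poly(A) RNA, polysome RNA, total RNA or rRNA-depleted RNA. Samples were assigned to groups from their titles, descriptions and characteristics.

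The authors deposited RPKM, a read count scaled to gene length and library size, for 15399 gene identifiers in 1 table of 28 columns. Of these, 13 columns were taken as poly(A) libraries and 15 held the free, middle and heavy gradient fractions of 5 polysome samples. Columns were matched to samples by name, and 18 of the 28 samples had a column. The other 10 samples, among them all total RNA and rRNA-depleted libraries, were not analysed here, so 2 planned contrasts over 3 kinds of library were not run. The oocyte column was assigned to the poly(A) library of oocytes with wall by inference, because the table is of mRNAs and that library is the only poly(A) oocyte library of the series. The column name alone does not decide this. The name of the 64 h column fits the poly(A), total RNA and rRNA-depleted libraries of 2-4-cell embryos alike. It was taken as the poly(A) library by the same inference, which the files do not settle. Per the series design text, sequencing strategies differed among libraries, and which library had which is not used here.

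Bowtie 0.12.7 is named by the submitters' processing notes, and the genome build, annotation and counting tool are not given in the sources used here. Deposited RPKM values had 1 decimal, with a smallest value above 0 of 0.1 or 0.2 in each column. No whole-read steps were seen in the pairs of libraries examined, so sequencing depth is unknown and no counting interval is given. Column totals ran from 311996 to 453746 RPKM over the 13 poly(A) columns and from 236086 to 918364 RPKM over the 15 fraction columns, and a further scaling between fractions is not excluded. The files do not pair identifiers with gene names, so the 25 gene lists fixed in advance were not tested. For each tested contrast at most 2 identifiers that rose and 2 that fell are printed, taken by size of the log2 fold change among genes with an adjusted p under 0.05 and the same sign in both preparations, or on all 5 days for gradient fractions. No such condition was applied to the slope per day.

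Tests used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with an intensity trend in the empirical Bayes step, Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A fold change on this scale understates the change of genes with low RPKM. Genes needed RPKM 1 in at least 2 libraries of a fit. The stage fit used 8 libraries, 1 poly(A) and 1 polysome library for each of zygote region 4, 1-cell, 32-64-cell and 256-cell embryos, with stage and preparation as terms and 3 residual degrees of freedom. The series design text treats poly(A) and polysome libraries of 1 sample as biological replicates, but they differ in preparation. Adjusted p-values of the stage fit therefore measure the spread between preparations after their average difference is removed. Whether the 2 libraries of a stage came from the same material is not known here. The design assumed 1 polysome value per sample. As the table held 3 fractions, the polysome value was their mean RPKM. A slope over uterus regions was fitted to 4 libraries with 2 residual degrees of freedom. Elsewhere a stage had 1 library, so values were compared without a test. A gene was counted as 4-fold apart on RPKM + 1 where at least 1 of the compared libraries reached RPKM 10.

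The comparison of gradient fractions was added after the table was seen, with fraction and day as terms over 15 columns and 8 residual degrees of freedom, and a slope per day for each fraction with 6. Gene classes set against that fit were also defined after the table was seen. An exploratory set with 12 separate onset libraries was looked at first, and the 6 classes reported here replaced it. Classes were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, fry and an exact sign-flip test over 5 days. Each class median was also placed among 10000 random lists matched on mean expression in 50 bins.

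The stage, fraction, uterus slope and slope-per-day fits were tested on simulated data with known changes. For each size of change 66 or 67 genes were altered, all upward, with noise independent between genes. For 1-cell embryos minus zygote region 4, over 12961 genes, 71.6% of genes changed by 2 on the log2 scale and 8.96% of those changed by 1 were recovered, with 16 false calls among 135. For polysome minus poly(A) RNA the shares were 95.5% and 32.8%, with 5 false calls among 157. For heavy minus free fractions, over 13771 genes, they were 94.0% and 28.4%, with 13 false calls among 161. For the uterus slope, over 11076 genes, 100% of genes with a slope of 2 log2 units per region and 95.5% with 1 were recovered. There were 12 false calls among 209, and smaller slopes were not simulated. For the slope of heavy minus free per day, over 13771 genes, 44.8% of genes with a slope of 0.4 and 0% of those with 0.2 log2 units per day were recovered, with 8 false calls among 97. In 4 of these 5 comparisons the share of false calls lay above the 0.05 aimed at. In the data many more genes were called, with 1452 of 12961 for polysome minus poly(A) RNA and 6790 of 13771 for heavy minus free. With so many calls the adjusted threshold is less strict, so the simulated shares do not carry over to those contrasts.

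Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter of RPKM 10, quantile normalization, median-ratio scaling, no intensity trend, no preparation term, 10 libraries and leaving out each library, or region 1 or region 4 for the uterus slope. For values without a test they were a fold of 2, RPKM 5 as present, median-ratio scaling and a pseudocount of 0.1. Descriptive values and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.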

Results

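Transcript levels were followed in Ascaris suum, a roundworm whose embryos begin as zygotes in the uterus and divide slowly after they are laid. The table held 13 poly(A) RNA libraries, from oocyte to L2 larva, and free, middle and heavy polysome gradient fractions from embryos of days 0, 1, 3, 5 and 7. Between 9255 genes at 116 h and 12146 genes in L1 larvae had RPKM 1 or more in the poly(A) libraries. The 10 most abundant genes took between 5.54% of the RPKM total at 24 h and 16.1% in the oocyte library, which was assigned to oocytes with wall by inference, as the 64 h library was to poly(A) RNA. Across genes, which are not independent replicates, log2 values of the poly(A) library and the polysome value of a stage had a Pearson r of 0.95 at zygote region 4, 0.939 at the 1-cell stage, 0.952 at 32-64 cells and 0.897 at 256 cells. The day 0 polysome value was closer to zygote region 1, with an r of 0.955, than to region 4.

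The first question was at which steps of development the RNA population differed. Neighbouring libraries differed most at both ends of the series. The oocyte and L2 libraries at these ends also had the most genes at 0, 23.1% and 29.8%, against at most 17.0% in other poly(A) libraries. L2 had 10804 genes above 0 and 10532 at RPKM 1 or more, so few values lay between. Whether depth adds to these steps was not tested. From oocyte to zygote region 1, 519 genes were at least 4-fold higher and 352 at least 4-fold lower. Zygote regions 1 and 2 differed by 1 gene, and 24 h and 46 h embryos by 14. From 64 h to 96 h, between 2-4 and 10-26 cells, 486 genes were 4-fold lower and 153 higher, and from 116 h to day 7 the direction was the opposite, with 309 higher and 37 lower. From day 7 to L1, 1214 genes were higher and 49 lower, and from L1 to L2 461 were higher and 1490 lower. ASU_01027 was at RPKM 8652 in the oocyte library and 11.3 in zygote region 1, while ASU_12097 was listed at 0 in the oocyte library and at 169.2 in region 1. Each stage had 1 library, so no step has a replicate check. As a yardstick, the poly(A) library and the polysome value of 1 stage differed 4-fold in 170 genes at zygote region 4, 217 at 1 cell, 445 at 32-64 cells and 730 at 256 cells. Only the steps from oocyte to zygote region 1, from day 7 to L1 and from L1 to L2 had more genes than the highest of these, and the 639 of the step from 64 h to 96 h lay between 445 and 730.

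**Figure D1:**
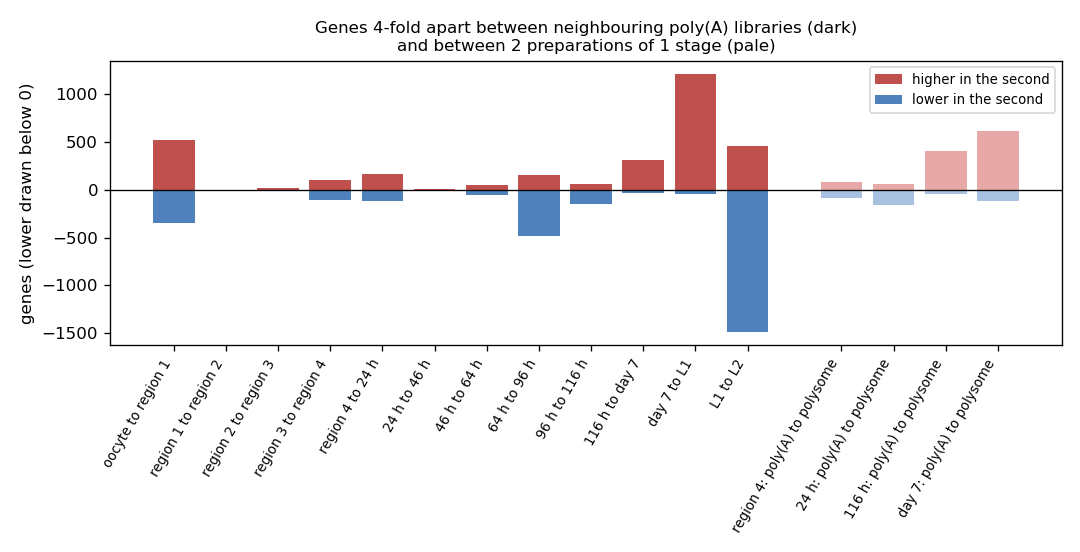
Number of genes at least 4-fold higher (above 0) or lower (below 0) on RPKM + 1 in the second of each pair of libraries; dark bars are neighbouring poly(A) libraries and pale bars are the poly(A) library and polysome value of 1 stage. The tallest bars are the 1490 genes lower in L2 than in L1 and the 1214 genes higher in L1 than on day 7. In the L2 library 29.8% of genes were at 0, against 5.41% in L1.

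The next comparison asked when RNAs low in the oocyte first appeared. Of 5342 genes under RPKM 1 in the oocyte library, 1680 reached RPKM 10 in a later library. Of these, 191 first reached it in the uterus regions, 62 already in region 1, and 151 more at 24 h, in 1-cell embryos. The libraries from 24 h to 64 h accounted for 282 genes, those from 96 h to day 7 for 282, and the 2 larval libraries for 925. Genes that reached RPKM 10 in the uterus had a median RPKM of 0.1 in the oocyte library, 13.7 in zygote region 4, 18.8 at 24 h and 2.9 at 116 h. Genes that reached it between 24 h and 64 h had a median of 2 in zygote region 4 and 12.5 at 46 h. These are values from 1 library per stage and rest on the inferred identity of the oocyte column. With RPKM 10 in the oocyte library as the start, 5958 genes were present, of which 421 were at least 4-fold lower in region 3, 254 in region 4, 624 at 24 h, 1325 at 64 h and 1736 at 116 h. The number was 1646 on day 7, 1382 in L1 and 2077 in L2. L2 had more genes at 0 than any other poly(A) library.

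**Figure D2:**
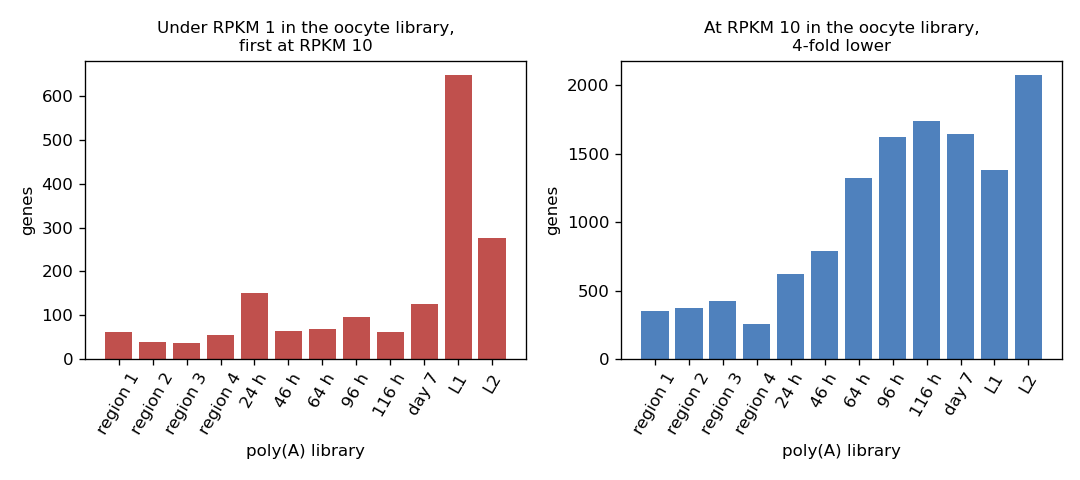
Left, genes under RPKM 1 in the oocyte library by the poly(A) library in which they first reached RPKM 10; right, genes at RPKM 10 or more in the oocyte library that were at least 4-fold lower on RPKM + 1 in each later library. The left panel has 151 genes at 24 h and 649 in L1; the right panel has 353 genes in region 1, 254 in region 4, 1736 at 116 h, 1382 in L1 and 2077 in L2.

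Passage through the uterus was examined as a slope over regions 1 to 4. None of 11076 genes had a slope past the threshold in limma, and 1041 had an unadjusted p under 0.05, where 553.8 would be expected by chance. The median slope of all genes was 0.12 log2 units per region. Without the region 4 library 1319 genes rose and 1503 fell over regions 1 to 3, without the region 3 library 396 rose and 124 fell, and without the region 2 library 1 rose and 15 fell; those fits had fewer residual degrees of freedom, and leaving out region 1 gave 0 genes. ASU_06141, chosen after its values were seen, was at RPKM 0.4 in the oocyte library, 350.5, 561.8 and 1546 in regions 1 to 3 and 140.3 in region 4.

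Over the 4 stages with both preparations, from zygote region 4 to 256 cells, 7571 of 12961 genes changed in the moderated F-test. The changes were unevenly spread, and the step from 1 cell to 32-64 cells had 5386 calls against 206 and 1005 for the steps on either side. These steps differ in length, so the counts do not compare rates. In the poly(A) libraries the middle step ran from 24 h to 116 h, past the 46 h, 64 h and 96 h libraries. The step before it ran from 0 h to 24 h and the step after it from 116 h to day 7. The median standard error of a step was 0.46 log2 units, with 2 libraries per stage.

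Between zygote region 4 and the 1-cell embryo, 173 genes rose and 33 fell. The genes that rose were nearly silent before, with a median RPKM of 1 in the zygote library, 11.5 at 24 h, 13.7 at 46 h and 1.3 at 116 h. The genes that fell had a median of 52.9 in the zygote library and 12.6 at 24 h. The median log2 change of those that rose was 2.19 and of those that fell -1.93. ASU_12228 rose by 4.11 ± 0.50 (SE, limma adjusted p = 0.00133), from RPKM 1.5 to 57.8 in the poly(A) libraries, and ASU_11227 rose by 4.04 ± 0.45 (adjusted p = 0.00101). ASU_09331 had a log2 change of -2.51 ± 0.44 (adjusted p = 0.0123) and ASU_08091 of -2.46 ± 0.60 (adjusted p = 0.0485), which was -1.33 and no longer called without the region 4 poly(A) library and -3.59 without the polysome one. The ASU_09331 call was also lost without the region 4 poly(A) library. Both falling genes lost their calls with a pseudocount of 5, with no filter and with each other polysome value, and ASU_08091 also without the intensity trend, with 10 libraries and without the 1-cell poly(A) library. The call of ASU_12228 was lost with a pseudocount of 5, and those of ASU_12228 and ASU_11227 with the mean of log2 fractions. The count was not stable: it was 0 without the preparation term and 0 without either 32-64-cell library, 715 without either 256-cell library and 111 without the region 4 poly(A) library. Leaving out the 1-cell poly(A) library turned the direction, with 29 genes up and 91 down, leaving out the region 4 polysome library gave 68 up and 66 down, and leaving out the 1-cell polysome library 361 up and 23 down. In other scalings 683 rose and 405 fell after quantile normalization, and 839 rose and 877 fell after median-ratio scaling.

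From the 1-cell to the 32-64-cell embryo 2158 genes rose and 3228 fell. Genes that fell went from a median RPKM of 9.45 at 24 h to 0.4 at 116 h, with 3.5 at 64 h and 0.9 at 96 h between. Genes that rose had a median of 10.3 at 24 h and 28.4 at 116 h. ASU_03503 rose by 10.76 ± 0.39 (limma adjusted p = 3.64e-11), from RPKM 1.5 at 24 h through 103.4 at 64 h to 3330.2 at 116 h, and ASU_05171, listed at 0 in the first 8 poly(A) libraries, was at 247.2 at 116 h and 525.1 on day 7. ASU_14992 fell from RPKM 628.7 at 24 h to 1.4 at 116 h in the poly(A) libraries and from 476.5 to 29.4 in the polysome values (adjusted p = 2.48e-05), log2 changes of -8.04 and -3.97. ASU_09456 fell by less in the polysome values too, with log2 changes of -7.82 and -4.18 (adjusted p = 1.08e-05). Without the 32-64-cell poly(A) library the fitted changes were -4.22 and -4.37, both still called. More genes fell than rose as deposited and after median-ratio scaling, with 3284 up and 4053 down, but not after quantile normalization, with 3458 up and 3074 down, nor with a filter of RPKM 10, with 2025 up and 1872 down. Without the 1-cell poly(A) library 2245 rose and 2018 fell, without the 32-64-cell poly(A) library 1963 rose and 1591 fell, and without the polysome one 791 rose and 2400 fell.

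From 32-64 to 256 cells 849 genes rose and 156 fell. The genes that rose had a median RPKM of 0.6 at 116 h, 7.2 on day 7 and 21.4 in L1, and had also been low in the oocyte library, at 1.3. The genes that fell had a median of 29.65 at 116 h and 5.45 on day 7. ASU_09187 rose by 6.46 ± 0.55 (limma adjusted p = 7.24e-06) and was at RPKM 157.5 on day 7 and 739 in L1, while ASU_05094, with a log2 change of 6.42 ± 0.60, was at 123.1 on day 7 and 14.9 in L1. ASU_00237 had a log2 change of -3.42 ± 0.48 and ASU_03201 of -3.30 ± 0.48. More genes rose than fell under each scaling, with 929 up and 437 down after quantile normalization and 1304 up and 576 down after median-ratio scaling, but 167 genes were called without the 32-64-cell poly(A) library and 280 without the polysome one, and 506 without the 256-cell polysome library.

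Polysome RNA was compared with poly(A) RNA at the same stages. Of 12961 genes, 986 were higher in polysome RNA and 466 lower. The polysome value includes the free fraction, so a higher value does not by itself mean more RNA on ribosomes. On day 0 the 986 genes had median RPKM of 44.05 (free), 54.95 (middle) and 14.45 (heavy), against 18.05 in the poly(A) library. Their heavy median was also below poly(A) RNA on day 1, at 9.25 against 13.15. It was above on day 5, at 13.1 against 3, and on day 7, at 27.15 against 4.2. The higher group was more abundant in the early libraries, with a median poly(A) RPKM of 22.15 in the oocyte and 3 at 116 h. The lower group had 12.1 and 23.3. Both groups were called from the poly(A) libraries of region 4, 24 h, 116 h and day 7 and the polysome values. Their contrasts in those libraries and in the fractions are therefore partly set by the selection. The oocyte library was not in that fit. ASU_06415 was listed at 0 in all 13 poly(A) libraries and had a polysome value of 235.2 on day 0 and 239.3 on day 7. ASU_15443 had a log2 difference of -4.09 ± 0.42 (limma adjusted p = 2.8e-05). The split between higher and lower turned after quantile normalization, to 1061 higher and 1345 lower, but not after median-ratio scaling, with 2183 higher and 1466 lower. It turned with another polysome value, to 91 higher and 147 lower for the heavy fraction and 531 higher and 1705 lower for the mean of log2 fractions, whereas the middle fraction gave 2182 higher and 125 lower. It also turned without the 32-64-cell poly(A) library, with 170 higher and 190 lower, and without the polysome one, with 209 and 241. Without the poly(A) or the polysome library of 256 cells 807 or 806 genes were called.

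In a polysome gradient RNA on many ribosomes sediments furthest and RNA free of them least, and the comparison of fractions was chosen after the table was seen. Over 5 days and 13771 genes, 4097 were higher in the heavy than in the free fraction and 2693 lower. Genes higher in the heavy fraction had median poly(A) RPKM of 21.1 at 24 h and 20.4 at 116 h, and genes higher in the free fraction had 7.8 and 1.2. ASU_15077 was higher in the heavy fraction by 4.46 ± 0.44 log2 units (limma adjusted p = 3.11e-06) and ASU_06414 by 4.31 ± 0.43. ASU_14095 had a difference of -4.41 ± 0.45 and ASU_12142 of -3.70 ± 0.35. The same sign on all 5 days was a condition for printing these genes. Their SE measures variation between days, not between replicate gradients. For middle minus free the split was 7442 higher and 330 lower, and for heavy minus middle 43 higher and 6900 lower, with 4067 calls without day 1 and 3919 without day 3. The median of all genes moved with the scaling, from 0.12 to -0.05 (quantile) and -0.37 (median ratio) for heavy minus free and from 0.92 to -0.03 and -0.28 for middle minus free. The splits became 3705 higher and 3761 lower after quantile normalization and 3053 and 5358 after median-ratio scaling for heavy minus free, 3121 and 3035, then 2748 and 4529, for middle minus free, and 424 and 324, then 370 and 191, for heavy minus middle, so the direction of most genes between fractions is not free of the scaling.

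The gradient position of 6 gene classes taken from the poly(A) libraries was set against that of the other genes, and no class had a call that held with an estimated correlation. The class lower at 116 h held 1720 tested genes, at RPKM 10 in the oocyte library and at least 4-fold lower at 116 h. Their median heavy minus free difference was 0.58 log2 units below that of the other genes, coded as -0.58. Of them, 561 were lower in the heavy fraction and 236 higher. The other genes include the kept class, 4221 oocyte genes not 4-fold lower at 116 h, with a median of 0.94. All genes outside the kept class had a median of -0.10, against -0.39 for the class lower at 116 h. Part of the -0.58 therefore reflects the kept genes. The relative difference was negative on all 5 days, at -0.62, -0.79, -0.85, -0.53 and -0.29. The class's own median was -0.86 on day 0, -0.91 on day 1 and -0.85 on day 3. It was 0.28 on day 5 and 0.43 on day 7, towards the heavy fraction, where the other genes had 0.82 and 0.72. For middle minus free the relative difference did not keep 1 sign. It was -0.05 on day 0, 0.09 on day 1, -0.24 on day 3, -0.69 on day 5 and -0.46 on day 7. The 4221 oocyte genes not 4-fold lower at 116 h lay 1.04 above the others, with 2220 higher and 551 lower. Genes that reached RPKM 10 in the uterus lay at -0.35, those of 24 h to 64 h at -0.01, those of 96 h to day 7 at 0.10 and those of larvae at -0.30. In camera with the preset correlation the adjusted p was 1.94e-06 for the class lower at 116 h, 1.25e-10 for the kept class, 0.0245 for the uterus class, 0.000282 for the larval class, 0.335 for 24 h to 64 h and 0.69 for 96 h to day 7. Every one of these calls was lost with an estimated correlation (camera adjusted p = 0.613 for the first 4 classes named). Fry, which asks whether a class moved on balance between fractions and does not set it against other genes, gave adjusted p = 0.314 for the class lower at 116 h and 0.0625 for the kept class. The relative difference of the uterus class too was negative on all 5 days, at -0.36, -0.41, -0.47, -0.62 and -0.47. That of the kept class was positive on all 5. The uterus class's own median was above 0 on day 5, at 0.12, and day 7, at 0.21. The kept class's own median was -0.04 on day 0. For each of these 3 classes an exact two-sided sign-flip test of the relative difference over 5 days gave p = 0.0625, the smallest it can give, and 0.125 after adjustment over 6 classes. The median of the class lower at 116 h lay below all 10000 expression-matched random lists, but so did that of the uterus class. The class of 24 h to 64 h lay above only 1.2% of its lists, with a difference of -0.01. Genes of the kept class could be drawn into all these lists. The kept class lay above all of its lists, the class of 96 h to day 7 above 66.5%, and the larval class, lower in camera, above 99.2%.

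**Figure D3:**
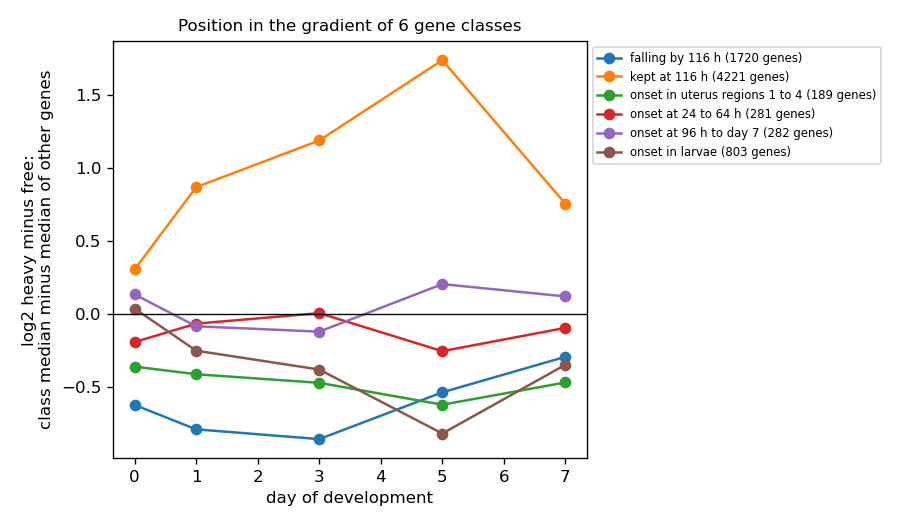
Median log2 heavy minus free difference of 6 gene classes minus that of all other genes, by day of development, 1 free and 1 heavy column per day; the legend calls the class lower at 116 h falling and gives the genes tested. Relative to other genes that class is below 0 on all 5 days, between -0.85 and -0.29, and the kept class is above 0 on all 5 days. The own median of the class lower at 116 h was 0.28 on day 5 and 0.43 on day 7.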

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

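The tests of gradient fractions in this part were chosen after the table was seen. The heavy minus free difference changed linearly with day in 2010 of 13771 genes, 1960 with a positive slope and 50 with a negative one, by a limma interaction of fraction and day. The median of all genes went from -0.26 on day 0 to 0.68 on day 7, so most genes shared the movement. After quantile normalization 40 genes were called, after median-ratio scaling 16, and without the day 1 columns 0. Without day 0 there were 538, without day 3 748, without day 5 1202 and without day 7 3825. ASU_15325 had a slope of 0.90 ± 0.18 log2 units per day (SE, adjusted p = 0.0118) and ASU_08406 of 0.80 ± 0.12, while ASU_12006 had -0.65 ± 0.14 and ASU_05016 -0.58 ± 0.12. The 4 calls were lost without day 1. The ASU_15325 call was also lost after both scalings and without day 7, that of ASU_08406 after median-ratio scaling, that of ASU_12006 after median-ratio scaling, with a pseudocount of 0.1 and without day 0, and that of ASU_05016 without day 0. With pseudocounts of 0.1 and 5 the slope of ASU_05016 was -1.14 and -0.26, and that of ASU_15325 was 1.39 and 0.51. Without day 7 the slope of ASU_12006 was -1.07.

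The lower gradient position, relative to other genes, of oocyte genes that were 4-fold lower at 116 h was weighed against 2 technical explanations. Of the 2 definitions of this class looked at, the first took genes 4-fold lower at 96 h, 116 h and day 7. It gave -0.68, -1.37, -1.85, -1.54 and -0.49 relative to all genes on the 5 days. That first version kept only genes at RPKM 5 in a fraction, so it differs from the reported one in more than the class. Scaling of the fraction columns by a factor each mostly cancels in the difference between the class lower at 116 h and other genes. That difference was -0.65 after quantile normalization, against -0.58 as deposited, with an SD over days of 0.22. The difference would hardly change with the scaling whether or not such a factor was the cause, so the value after quantile normalization cannot decide. As the whole cause, low RPKM values and the pseudocount predicted no difference among genes at RPKM 10 in 2 fractions, where it was -1.19. That cannot decide, because the filter can be met on day 0 alone and class genes can be low on later days. It also changes which other genes are compared. The difference was -0.38 with a pseudocount of 5 and -0.44 with no filter, against -0.58, so low values and the pseudocount both move its size. Fragmented RNA at the top of the gradient was not tested, and no biological explanation was tested. For middle minus free the class lay at -0.05 on day 0 and 0.09 on day 1. The test across genes did not hold with an estimated correlation.

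Other splits of the libraries were counted for both preparation contrasts. For polysome minus poly(A) RNA the real split called 1452 genes. Only 8 splits part every pair of libraries of a stage, the highest other of them called 0 genes, and the splits are too few for a share under 0.05. Of all 32 splits, most of which leave some pairs together, the highest other called 680. For heavy minus free over the 10 free and heavy columns the real split called 5694 genes. The highest other of the 16 splits that part all 5 days called 0, and these splits too are too few for a share under 0.05. The highest other of 100 splits, these 16 among them, called 3662 and left some days together.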

How the results depend on the processing

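Alternatives to the polysome value, to the fraction comparisons and to the class lower at 116 h, and the uterus slopes without region 2 or region 3, were chosen after seeing the data. For each departure given here the cause was not tested. Of 522 log2 fold changes under alternatives, of all identifiers that the naming rule took, printed or not, 471 kept their direction and call. Another 51 kept only their direction and 0 reversed. The rule took the largest changes and, slopes apart, required 1 sign in both preparations or on all 5 days. Reversals were therefore unlikely from the start. With no filter, no intensity trend or no replicate block the log2 value cannot change. These counts are no test of stability. The 3-kinds-of-library contrasts and the gene lists were not run.
The step from zygote region 4 to 1 cell had 206 calls, and 8 with a pseudocount of 5, 21 with no filter, 328 with a filter of RPKM 10, 1088 with quantile normalization, 1716 with median-ratio scaling, 92 without the intensity trend, 0 without the preparation term (no replicate block), 8 with the middle fraction, 29 with the heavy fraction and 0 with the mean of log2 fractions. The step to 32-64 cells had 5386, and 3569 without the preparation term and 2658 with the heavy fraction. The step to 256 cells had 1005, and 641 with a pseudocount of 5, 1880 with median-ratio scaling, 382 without the preparation term and 538 with the heavy fraction. The F-test had 7571, and 4894 with the heavy fraction.
Polysome minus poly(A) RNA had 1452 calls, and 670 with a pseudocount of 5, 685 with no filter, 2406 with quantile normalization, 3649 with median-ratio scaling, 8 without the stage term (no replicate block), 2691 with 10 libraries, 2307 with the middle fraction, 238 with the heavy fraction and 2236 with the mean of log2 fractions.
Heavy minus free had 6790, and 3027 without the day term; middle minus free 7772 and 5029; heavy minus middle 6943 and 245, with 748 after quantile normalization and 561 after median-ratio scaling. The slope per day had 2010, and 40 and 16 after those scalings. The class lower at 116 h moved from -0.58 to -1.19 with a filter of RPKM 10 and to -0.38 with a pseudocount of 5. Under the exploratory definition the value was -1.19. That version also kept only genes at RPKM 5 in a fraction and was set against all genes, so the change is not due to the definition alone. Neighbouring libraries differed in 5913 cases, 19278 with a fold of 2.
Leaving out 1 library gave 0 to 715 calls for zygote region 4 to 1 cell, 3191 to 5603 for 1 to 32-64 cells, 167 to 1432 for 32-64 to 256 cells, 360 to 1873 for polysome minus poly(A) RNA, 6111 to 7676 for the F-test and 0 to 2822 for the uterus slope, the last without region 4, with 520 without region 3 and 16 without region 2. Leaving out 1 day gave 5099 to 6664 for heavy minus free, 6800 to 7593 for middle minus free, 3919 (day 3) to 7730 for heavy minus middle, 0 to 3825 for the slope and -0.74 to -0.50 for the class. A left-out library leaves a stage with 1 library, which is assumed to vary like the others. Depth is unknown, so no limit from counting is given.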

Other observations

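The tests of this part were chosen after the result was seen. Genes under RPKM 2 in all 13 poly(A) libraries numbered 1915. Of these, 41 had a polysome value of RPKM 10 or more on day 7, 14 on day 0, 3 on day 1, 6 on day 3 and 7 on day 5. The 41 genes, taken for their day 7 value, had a median polysome value of 22.7 on that day, 5.17 on day 0, 0.667 on day 1, 2.83 on day 3 and 2.37 on day 5. ASU_15313, the second by polysome value, was at 165.8 on day 7.

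The zygote region 3 and 64 h libraries departed alike from their neighbours. Across 10818 genes, which are not independent replicates, the departures from the mean of the 2 adjacent libraries had a Pearson r of 0.536 (Spearman's rho 0.56), against at most 0.164 in 35 other pairs of libraries that share no neighbour, and 174 genes were at least doubled in both, where 19.1 would be expected from independent lists. Simple mixing of 2-4-cell RNA into the zygotes is argued against, since 9 genes abundant at 64 h and low in the other regions had a median region 3 to 64 h ratio of 0.0148, where the 174 genes had 1.4. Mixing in the other direction is argued against by a median 64 h to region 3 ratio of 0.0037 over 26 genes. A batch shared by the 2 libraries may be the source: the 174 genes had a median log2 deviation of -0.20 on day 3 in the polysome values, against -0.28 for other genes, so they did not stand out there. Day 3 is a later stage than 64 h, so a brief rise in these embryos stays open and untested, and the labels give no batch. That the 64 h column is a poly(A) library is itself inferred.

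Genes with adjacent identifiers had similar profiles over the 13 poly(A) libraries. Across 8144 adjacent pairs the mean r of centred profiles was 0.153, against at most 0.0289 in 1000 shuffles of the identifiers (permutation p = 0.001, the smallest they can give), and it was 0.0658 at a distance of 2 and 0.00895 at a distance of 10. Among 364 adjacent pairs with r above 0.9, 42.6% had a peak RPKM within 1.5-fold of each other, 17.7 percentage points above the 24.9% of random pairs with such an r. Pieces of 1 gene split over adjacent identifiers could account for part of this, and the share does not decide between that and neighbouring genes with shared regulation. These cannot be told apart here because no gene coordinates were used.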
